A study of Rattus norvegicus with 6 samples.

How the data were processed

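Liver RNA from 6 male Sprague-Dawley rats was measured, 3 rats given corn oil and 3 given 2,2-bis(bromomethyl)-1,3-propanediol (BBMP, a brominated flame retardant) at 1000 mg/kg/day, with 1 array per animal. Groups and replicate numbers were taken from the labels. The labels give the time in 2 ways: the series design gives 28 days and the treatment protocol gives 9 weeks. The sample titles also carry 28, and the rats were 5 weeks old at purchase per the labels. The 9 weeks may therefore be the age at the end of a 28-day exposure, but the files do not say so. Per the labels' protocols, 0.2 µg of RNA was labelled with Cy3 for 1-colour hybridisation. Per the file headers, the arrays (Agilent rat design 035170, annotated on the rat build rn4) were read with Feature Extraction 10.7.1.1, which subtracted the background, removed spatial trends and replaced the lowest values by small values above 0. The submitters' processing notes name Agilent Feature Extraction 10.7.

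The deposited scanner files hold each spot's brightness as linear intensity, not normalised between arrays. The authors' value table also holds linear intensity. Set against the scanner files, each of its columns was the processed signal divided by 1 constant near that array's 75th percentile, with column medians from 0.0971 to 0.1005 and no centring of probes. The purpose and software of that step are not given in the sources used here.

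Each array held 62976 spots, of which 1319 were control spots. A further 84 probes for external spike-in RNA, not marked as controls in the files, were left out as well, which left 61573 probes. Probes were named through their unversioned accession in the RefSeq gene table of the GRCr8 assembly, because the scanner files carried accessions and no gene symbols. This named 27460 probes (44.6%) and 15284 genes. Probes without a match kept their accession or probe name, which gave 45793 features in all.

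The log2 of the processed signal minus the log2 of each array's 75th percentile was analysed. The 75th percentile lay between 450.1 and 570.4 intensity units, and between 36988 and 39631 probes per array (60.1% to 64.4%) were well above background. Spots marked as outliers by the scanner software, at most 21 per array, were left out, and saturated spots were kept. A feature was tested if its probe was well above background on all 3 arrays of at least 1 group, and a gene with several such probes was represented by the probe with the highest mean over the 6 arrays. The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no covariate), two-sided, with Benjamini-Hochberg adjustment over 28112 features and a threshold of 0.05. Tables were made with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6.

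A total of 37 gene lists of liver pathways and of cell types that a liver sample can hold were tested with camera at its preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. The same lists were tested with an estimated correlation and with fry. Camera and fry used features without missing values. A list's score on an array was the mean over its members of the log2 signal minus the member's mean over the 6 arrays. Where a gene was not well above background on any array of 1 group, the difference was given as a lower bound: the bright group's mean against the dim group's mean of, per array, the higher of the probe's own signal and the lowest signal among probes well above background.

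The genes named in the text were set by a rule. It takes up to 12 rises and 12 falls among genes past adjusted p 0.05 and 2-fold that are well above background on all 6 arrays with groups that do not overlap; up to 4 members of each list with a member past adjusted p 0.05; up to 2 members with the smallest p of each other list described; the 5 genes with the largest lower bound; and, where fewer than 5 genes meet its opening part, the 10 genes with the smallest p. Here 0 genes met the opening part, and the 10 genes were taken among those with a symbol. Other genes are named as chosen after their values were seen.

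The alternatives were normexp background correction with an offset of 50, quantile normalisation, median scaling, no filter, a filter on all 6 arrays, every probe as its own row, the mean of a gene's probes, a mean-variance trend with robust moderation, the authors' value table, the replicate number as a block, an unmoderated unequal-variance test and leaving out each array in turn. Normexp was planned on the mean spot signal and was run on the median spot signal, since the scanner files used here carried that column. The scaling alternatives, normexp, the value table and the fits without 1 array used the same probe per gene. The groups, tests, lists, naming rule and alternatives were fixed before the data were examined. The fit was tested on simulated data with 200 of 28112 features changed: it recovered 47% of changes of 1 on the log2 scale, 86.9% of changes of 2 and 94.65% of changes of 3. Lists of 30 features shifted by 0.25 were called in 100% of 40 simulations and unshifted ones in 5%; the simulated features varied independently, unlike real genes of a pathway.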

Results

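Gene expression was measured in the livers of male Sprague-Dawley rats given corn oil, the vehicle (n = 3), or BBMP at 1000 mg/kg/day (n = 3), on 1-colour Agilent arrays with 1 array per animal. On the arrays, 60.1% to 64.4% of 61573 probes were well above background, and the number of arrays limits the precision. Pearson correlations between arrays, across 28112 features, lay between 0.986 and 0.992, and no pair of arrays was a duplicate. The main component of variation held 32.9% of the variance and parted the groups, with corn oil 2 farthest out at -50.84 against -9.60 and -14.82 for the other corn oil livers and 19.09 to 28.70 for the treated livers. All corn oil arrays were on 1 slide and scan and all treated arrays on another, so slide, scan and treatment cannot be told apart for any difference given here.

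The comparison asks which liver genes differ after BBMP. Expression of Clca2, a member of the calcium-activated chloride channel regulator family, was lost from the measurable range. Its probe was well above background in all 3 corn oil livers and in 0 treated livers, which puts it at least 9.91-fold lower after BBMP. The measured log2 difference was -5.04 (limma adjusted p = 0.00407). The p beside this and the other bounds below is for the measured difference, which rests on signals near background in 1 group, and does not test the bound. Genes of cholesterol synthesis, of the acute phase and complement, and of growth hormone and IGF signalling were shifted downward as groups. Targets of the xenobiotic receptors CAR and PXR, among them the Cyp2b enzymes, and genes of the cell cycle were shifted upward. These group shifts were past the threshold with camera's preset correlation, and none was with a correlation estimated from the 6 arrays.

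Of the 28112 features, 11114 of them named genes, 2 passed limma's adjusted p of 0.05: 0 were higher and 2 were lower after BBMP, both by more than 2-fold. The other feature, the unnamed probe A_64_P060879, was also not well above background in any treated liver and was at least 5.64-fold lower (adjusted p = 0.0290). At an unadjusted p under 0.05 there were 3035 features, 1321 higher and 1714 lower, where chance gives 1405.6; without corn oil 2 there were 1934, and the other splits of the 6 animals gave up to 2031. The groups did not overlap for 5018 features (17.85%), where chance gives 10% on average. This share was not computed for the other splits, so how far it varies between them is not known. Without corn oil 3, and likewise in the unmoderated test, with normexp and with a filter on all 6 arrays, 0 features passed. Without corn oil 2 the number was 4, of which 2 were higher. Without corn oil 1 it was 3, of which 1 was higher.

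Other genes with the smallest p did not pass over all features. A1bg, which encodes a plasma glycoprotein and is expressed more in female than in male rat liver, was well above background in 3 corn oil livers and 0 treated livers, at least 2.60-fold lower (limma adjusted p = 0.134). Dgat2l6 differed by -1.49 ± 0.16 on the log2 scale (SE; limma adjusted p = 0.269). Adjusted p was 0.314 for the rest. The difference was 1.13 ± 0.17 for Pip4p2, a phosphoinositide phosphatase, and 0.77 ± 0.12 for Knstrn, a component of the mitotic spindle. It was -0.77 ± 0.11 for the AP-1 transcription factor Jund, -0.65 ± 0.10 for the tetraspanin Tspan33 and -0.57 ± 0.09 for Mier3. Adam4l1, not well above background in any treated liver, was at least 1.64-fold lower. Among further genes seen in 1 group alone, Plppr1 was at least 2.18-fold lower (adjusted p = 0.379) and Fkbp10, a collagen chaperone, at least 1.75-fold lower (adjusted p = 0.401). Zfp362 was at least 2.46-fold higher on the group mean (adjusted p = 0.533), with -1.87 in BBMP 1 against -4.68 and -4.77 in the other treated livers.

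**Figure D1:**
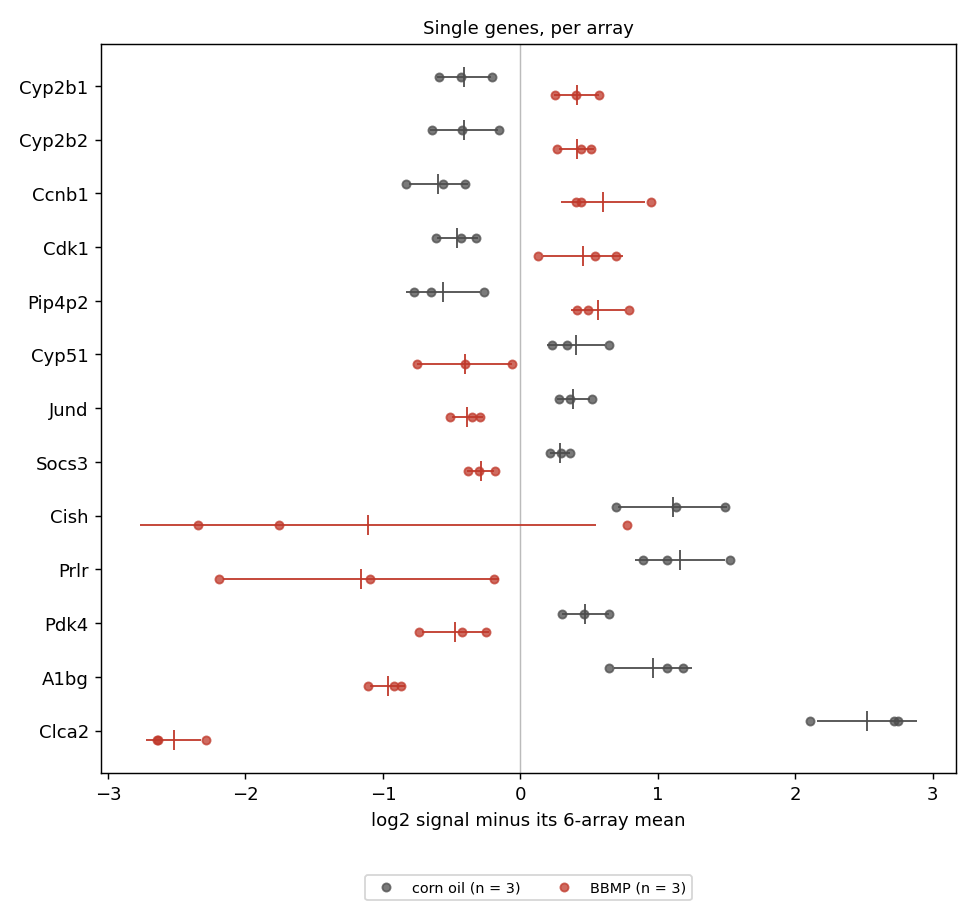
Log2 signal of 13 genes on each array, minus the gene's mean over the 6 arrays (horizontal axis, log2 units), with corn oil in grey and BBMP in red; each point is 1 liver, the tick is the group mean and the line 1 SD. Clca2 and A1bg were not well above background in any treated liver, so their red points mark signal near background, and Cish overlapped between the groups.

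The CAR and PXR target list held 31 tested genes, 24 higher and 7 lower, with a mean log2 difference of 0.34. Its score was 0.17 ± 0.02 in treated and -0.17 ± 0.19 in corn oil livers (SD), without overlap. Camera gave an adjusted p of 1.0e-04, and the adjusted p was 0.66 with an estimated correlation. Over all features 0 members passed, while adjusted over the list alone 6 rose and 2 fell. Cyp2b1 and Cyp2b2, the phenobarbital-inducible cytochromes P450, differed by 0.82 ± 0.14 and 0.82 ± 0.15 (SE), and Cyp2b15 by 0.59 ± 0.10 and Cyp2b12 by 0.62 ± 0.12. Probes of these near-identical copies can bind each other's transcripts, and another probe of Cyp2b15 gave -0.20. The other members past the list's own threshold, chosen after their values were seen like Cyp2b2 and Cyp2b12, were Cyp2a1 (0.45), the carboxylesterase Ces2c (1.14), the export pump Abcc2 (-0.37) and the oestrogen sulfotransferase Sult1e1 (-0.39). No Cyp3a member of the list was past that threshold.

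The cholesterol synthesis list had 26 of its 28 tested genes lower after BBMP, with a mean log2 difference of -0.28. Camera gave an adjusted p of 2.8e-05, and the adjusted p was 0.66 with an estimated correlation. No member passed over all features, and 0 passed adjusted over the list alone. Cyp51, the sterol 14-demethylase, differed by -0.81 ± 0.20 and Srebf2, the transcription factor that drives the pathway, by -0.38 ± 0.10 (SE). The list scores overlapped: treated livers ranged from -0.41 to 0.08 and corn oil livers from -0.01 to 0.30. Without BBMP 3 the mean difference was -0.15.

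The cell cycle list had 20 of 28 tested genes higher, with a mean log2 difference of 0.30. Camera gave an adjusted p of 1.0e-04, and the adjusted p was 0.66 with an estimated correlation. Over all features 0 members passed and adjusted over the list alone 4 rose. These were the mitotic cyclin Ccnb1 (1.20 ± 0.19, SE) and its kinase Cdk1 (0.92 ± 0.17) and, chosen after their values were seen, Prc1 (0.80) and Bub1 (0.51). Ccnb1 and Prc1 were dim in corn oil livers, with mean log2 signals of -4.25 and -4.14. The lowest signal among probes well above background lay between -5.40 and -4.89 on those arrays, so both genes lay near the limit of measurement. Scores did not overlap, but treated livers were spread from -0.02 in BBMP 1 to 0.37 in BBMP 3, and without BBMP 3 the mean difference was 0.19. The macrophage and Kupffer cell marker list was also past camera's threshold upward (16 of 19 genes higher, adjusted p = 0.0270; adjusted p = 0.79 with an estimated correlation), with 0 members past either threshold. Its scores varied as much within the groups as between them, from -0.33 to 0.29 in corn oil and from -0.26 to 0.44 in treated livers. Vsig4, a Kupffer cell receptor, differed by 0.55 ± 0.27 and Trem2 by -0.41 ± 0.19.

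Growth hormone and IGF signalling genes were lower in 13 of 16 cases, with a mean log2 difference of -0.37 and a median of -0.26. The mean rests largely on Cish and Socs2, given below. The scores of the groups did not overlap. Camera gave an adjusted p of 6.8e-04, and the adjusted p was 0.55 with an estimated correlation. Over all features 0 members passed, and adjusted over the list alone 2 fell: Socs3, a feedback inhibitor of cytokine signalling (-0.58 ± 0.10, SE), and the growth factor Igf2 (-0.51 ± 0.10). Of members chosen after their values were seen, the STAT5 targets Cish and Socs2 differed by -2.21 ± 0.78 and -1.55 ± 0.64 and varied widely between animals, with Cish at 0.98 in BBMP 1 against -1.55 and -2.14 in the other treated livers. Igf1, the main secreted growth factor of the liver, differed by -0.28 ± 0.12. In the acute phase and complement list 29 of 36 genes were lower, with a mean of -0.16 (camera adjusted p = 2.7e-04; adjusted p = 0.66 with an estimated correlation). No member passed over all features, and adjusted over the list alone 1 fell, again Socs3; the fibrinogen chain Fga differed by -0.35 ± 0.11.

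The remaining 5 lists past camera's threshold had adjusted p between 0.66 and 0.68 with an estimated correlation, and 0 of their members passed over all features. For heat shock genes 10 of 11 were higher (camera adjusted p = 0.00912); adjusted over the list alone 1 rose, the small chaperone Cryab (0.45 ± 0.09, SE), and the mitochondrial chaperone Hspd1 differed by 0.33 ± 0.13. For PPAR-alpha targets, genes of fatty acid oxidation, 28 of 43 were higher (camera adjusted p = 0.0104). The only member past its threshold adjusted over the list alone went the other way: Pdk4, a kinase that restrains glucose oxidation, fell by 0.95 on the log2 scale. The peroxisomal genes Pex11a and, chosen after its values were seen, Ehhadh differed by 0.55 ± 0.11 and 1.07 ± 0.24. The Cyp4a members of the list differed by only -0.15 to 0.20. The list scores of the groups overlapped, with corn oil 1 at 0.12 and BBMP 2 at -0.02. Amino acid and urea genes were higher in 25 of 37 cases (camera adjusted p = 0.0104), with 0 past the threshold adjusted over the list alone; the glutaminase Gls2 differed by 0.44 ± 0.14 and the transaminase Gpt by 0.78 ± 0.26. Stellate cell and fibroblast markers were lower in 15 of 22 cases (camera adjusted p = 0.0165), also with 0 adjusted over the list alone; the retinol-storing enzyme Lrat differed by -0.49 ± 0.14 and the receptor Pdgfrb by -0.53 ± 0.16. Pericentral genes were lower in 13 of 18 cases (camera adjusted p = 0.0327); adjusted over the list alone 1 fell, the dicarboxylate transporter Slc13a3 (-0.75 ± 0.13), and Rgn differed by -0.86 ± 0.21. These 5 lists and the macrophage list each lost camera's threshold without certain single arrays. Heat shock lost it without corn oil 3 or BBMP 2 (adjusted p up to 0.0895), and PPAR-alpha targets without corn oil 2, corn oil 3 or BBMP 1 (up to 0.0984). Amino acid and urea genes lost it without corn oil 1 or BBMP 2 (up to 0.279), and stellate markers without BBMP 2 or BBMP 3 (up to 0.101). Pericentral genes lost it without corn oil 1 or BBMP 1 (up to 0.225), and macrophage markers without corn oil 1, corn oil 2, BBMP 1 or BBMP 3 (up to 0.476).

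**Figure D2:**
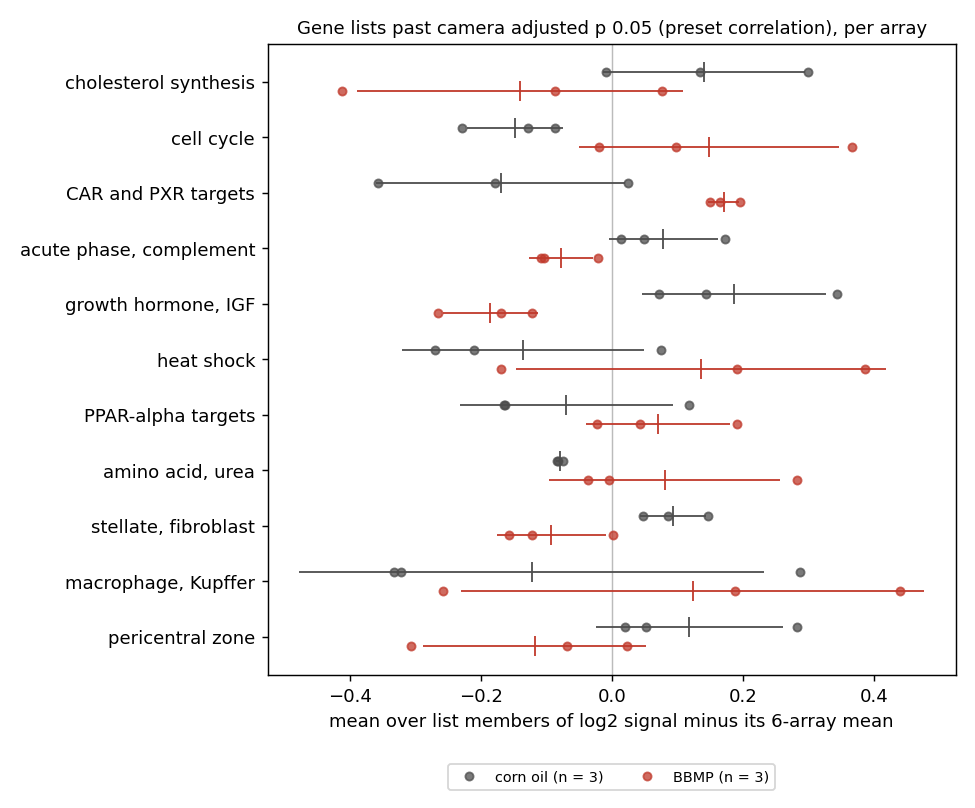
Scores of the 11 lists past camera's threshold with the preset correlation on each array: the mean over list members of the log2 signal minus its mean over the 6 arrays (horizontal axis, log2 units), with corn oil in grey and BBMP in red; each point is 1 liver, the tick is the group mean and the line 1 SD. CAR and PXR targets lay between 0.15 and 0.20 in the treated livers and between -0.36 and 0.02 in the corn oil livers, while the macrophage scores overlapped widely.

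Of the other 26 lists, with camera adjusted p from 0.0542 to 0.860, several concern responses often looked for after a reactive brominated compound. For p53 and DNA damage genes 11 of 23 were higher (camera adjusted p = 0.798), with Phlda3 at -0.94 ± 0.24 and Bbc3 at -0.49 ± 0.17 (SE). For NRF2 and glutathione genes 22 of 42 were higher (camera adjusted p = 0.559), with Gstm2 at 0.41 ± 0.13 and Tkt at -0.22 ± 0.10. For aryl hydrocarbon receptor targets 3 of 7 were higher (camera adjusted p = 0.311), with Cyp1a2 at -1.06 ± 0.30 and Aldh3a1 at -0.41 ± 0.15. In each of these 3 lists 0 members passed, over all features or adjusted over the list alone. A p that misses the threshold does not show that these genes were unaffected.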

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

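All alternatives were planned, though normexp was planned on the mean spot signal and run on the median. Over 28112 features, 2 passed, and 2 passed with a change of at least 2-fold. Both numbers fell to 0 with normexp, run with the median spot signal and an offset of 50 together, under which the difference of Clca2 was -1.57 against -5.04; to 0 with the filter on all 6 arrays, which removes both features by construction; to 0 with the unmoderated unequal-variance test; and to 1 without a filter, where 45793 features were tested. Except for the removal by construction, the cause was not tested. Without a filter, not only the number of features changed: the unadjusted limma p of Clca2 went from 1.4e-07 to 3.9e-07 at the same difference. Unadjusted p was under 0.05 for 3279, 2835, 2034 and 3308 features in these 4 settings. Leaving out 1 array gave 0 to 4 features for both numbers, 0 without corn oil 3 and 4 without corn oil 2. Clca2 passed in all of these fits except the one without corn oil 3. A_64_P060879 also failed to pass without BBMP 1, BBMP 2 or BBMP 3, where other features passed in its place. Quantile and median scaling, every probe, the mean of probes, the trend and the authors' value table gave 2, the same features each time. The replicate block gave 0 of both (3235 at an unadjusted p under 0.05); the numbers are not known to pair the animals. Same-numbered animals deviated together with correlations of 0.089, 0.016 and 0.072, and not every animal correlated best with its own number. The number of lists past the threshold was 11, went to 0 with an estimated correlation and to 0 with directional fry, and was 3 with mixed fry: acute phase, growth hormone and IGF, and female-enriched genes. Other settings gave 10 to 16 lists, 12 with the replicate block, and 8 to 11 without 1 array. Of the 58 features named in the text, 0 changed direction under an alternative and 2 changed sides of the threshold. They were chosen by their p, their bound or their values on these same arrays, so a stable direction was likely beforehand and shows little. Apart from Clca2 and A_64_P060879, none was past the threshold to begin with. The trend, the unmoderated test and the every-probe setting, followed for the main probe, keep the same difference, so the direction could not change there. The filter on all 6 arrays kept 51 of the 58. The other probe of Cyp2b15, at -0.20, was not part of this count. Signal over background limits Clca2, A_64_P060879, A1bg, Adam4l1, Plppr1, Fkbp10 and Zfp362 to a bound, since 1 group was not well above it.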

Other observations

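Of the tests in this part, the one on leukocyte markers, the comparisons of single lists between splits, the tests of the reduced CAR and PXR list and of the immediate early genes with an estimated correlation, and the overlap of the immediate early scores were chosen only after the result was seen.

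Of 16 genes that are female-enriched in rat liver, 8 were higher and 8 lower after BBMP (camera adjusted p = 0.392), and fry's mixed test gave an adjusted p of 0.0120, where camera under the other alternatives gave 0.0468 to 0.676. Over all features 0 passed; adjusted over the list alone 4 fell and 1 rose. A1bg and the prolactin receptor Prlr (-2.32 ± 0.49, SE) fell, as did, chosen after their values were seen, the steroid reductase Srd5a1 (-0.56) and the sulfotransferase Sult2a1 (-0.63), while Cyp2a1 rose (0.45). Prlr was lower in 3 of 3 treated livers than in every corn oil liver, at -2.86, -4.86 and -3.76 against -1.77 to -1.14. In the male-enriched list 12 of 19 genes were lower (camera adjusted p = 0.399) with 0 past the threshold adjusted over the list alone; Rgn and Sult1e1 had the smallest p.

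Lists that mark other cell types gave no common direction. Of those past camera's threshold with the preset correlation, described above, the macrophage list was higher and the stellate and fibroblast list lower. Endothelial markers were higher in 9 of 12 cases (camera adjusted p = 0.0542), T and NK cell markers lower in 13 of 18 (0.559) and neutrophil markers lower in 7 of 8 (0.335), none past the threshold. The mean, the median and the test differed in sign for 5 lists, none of them past the threshold: bile acid and transport, adipocyte, cholangiocyte, muscle and glucose metabolism.

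The 6 animals make 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 2 features past the threshold, and 2 at least 2-fold changed, where the highest of the other splits gave 1 for each. Thus 1 split, the real one, gave as many. All splits used the features kept by the background filter on the real groups. Both features of the real split were kept through the corn oil group alone. The filter therefore favoured the real split, and nothing is concluded from these counts of features. For lists the real split gave 11 and the highest other 10, again 1 split with as many. With 7 lists past the threshold, the split that set corn oil 1, corn oil 2 and BBMP 2 apart gave the macrophage list a camera p of 4.6e-25, with corn oil 3 scoring 0.29 and BBMP 2 scoring -0.26 against their groups' means of -0.12 and 0.12. Each of the other splits keeps 2 animals of each group together, so it carries part of the treatment contrast.

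CAR and PXR target genes were higher in treated livers with camera's preset correlation, a call lost with an estimated one (adjusted p = 0.66). With the preset correlation the largest adjusted camera p without 1 array was 9.6e-04. Camera at this correlation also called lists in the other splits, so that p cannot exclude a single animal as the cause. The mean difference stayed between 0.25 and 0.44 without any 1 array, so no single array held all of it. The list's median lay at percentile 100 of random lists matched on brightness, against a shift shared by probes of similar signal. The random lists drew genes independently, unlike the genes of a pathway. Lists not past camera's threshold also lay near the edge, such as male-enriched genes at percentile 1.85. The percentile therefore bears on brightness alone and does not set this list apart. Without its Cyp2b and Cyp3a members the list kept a mean of 0.34, so the difference was not confined to those copies. Its camera p was 0.00424, and 0.147 with an estimated correlation. Wrong splits gave the full list smaller camera p than 0.00424, so this p decides nothing about cross-hybridisation among those copies. The real split gave a camera p of 8.1e-06 and the smallest of the other splits 2.6e-04. The list was among those with the smallest camera p in the real split, which favours this order, so nothing is concluded from it. Slide and scan stay open because they cannot be told apart from treatment, so receptor activation by BBMP is a hypothesis that may be followed up in animals hybridised in mixed order.

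Cholesterol synthesis genes were lower in treated livers with camera's preset correlation, a call lost with an estimated one (adjusted p = 0.66), and 0 members passed singly. The median lay at percentile 0 of matched random lists, which argues against a shift by brightness and, as for the CAR and PXR list, bears on no other cause. With the preset correlation, the largest adjusted camera p without 1 array was 0.00474. A wrong split, given below, reached a smaller camera p, so this value cannot exclude that a single animal made the call. Without BBMP 3 the mean went from -0.28 to -0.15, and the scores of the groups still overlapped. Lower food intake could lower this pathway; the genes written as induced by fasting, 9 of them tested, gave a camera p of 0.623 and decide nothing. Another split, corn oil 1, corn oil 3 and BBMP 2 against the rest, gave the list a smaller camera p, 1.1e-09 against 7.5e-07 for the real one. Slide, scan and treatment cannot be told apart here either.

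Cell cycle genes were higher in treated livers with camera's preset correlation, a call lost with an estimated one (adjusted p = 0.66). The median lay at percentile 100 of matched random lists, against a shift by brightness, and this too bears on no other cause. With the preset correlation, the largest adjusted camera p without 1 array was 0.0229. A wrong split, given below, reached a smaller camera p, so this value cannot exclude that a single animal made the call. Without BBMP 3 the mean went from 0.30 to 0.19. More leukocytes could bring dividing cells: the test, run on T and NK markers (upper bound 0.019) and widened to B cell and macrophage markers after that value was seen (highest bound 0.368, macrophages, against a cell cycle mean of 0.30), took its bounds over genes and leaves out the spread between animals, so neither bound counts against this and it stays open. Another split gave a smaller camera p, 4.4e-08 against 7.3e-06, and slide and scan cannot be told apart from treatment.

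Jund was among the genes with the smallest p, and Sertad1 (-0.59), Gadd45g (-1.86) and Ier5 (-1.15), chosen after their values were seen, were lower too, none past the threshold over all features. A hypothesis is that immediate early genes, which respond within minutes to stimuli and to handling of tissue, may be lower as a class in treated livers. Of 21 others written down before their values were looked up, 19 were tested and 15 were lower, with a camera p of 0.0106, which met the bound set beforehand. A stricter reading was added after that value was seen: the p was 0.217 with an estimated correlation. Treated livers scored 0.010, -0.041 and -0.49 and corn oil livers 0.10, 0.44 and -0.020, so the groups overlapped, and on these added criteria the question stays open.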
